A study of Drosophila melanogaster with 5 samples.

How the data were processed

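Genomic DNA from hand-dissected Drosophila melanogaster egg chambers was compared with DNA from young diploid Oregon R embryos on 2-colour Agilent tiling arrays (comparative genomic hybridisation). There were 5 arrays, 1 per group: stage 13 egg chambers of wild type (Oregon R), the SuUR mutant, 4X-SuUR and 6X-SuUR, and stage 10B egg chambers of wild type. The 4 stage 13 arrays had 176936 spots, of which 173496 were genomic probes, with egg chamber DNA in Cy5. The stage 10B array was of another design with 950379 genomic probes and had egg chamber DNA in Cy3. Stage, array design, dye orientation and batch therefore cannot be told apart.

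The scanner files hold spot intensity values, which the authors deposited as Agilent Feature Extraction 10.1.1.1 wrote them. Per the file headers, the processed intensity of each channel was background-subtracted, detrended over the slide and scaled by a linear dye factor. Probe positions are on build dm3, per the file headers. A second file per array holds normalized log2 ratios of egg chamber over embryo, deposited by the authors. Per the file headers these log2 values are channel 1 over channel 2; the normalization method is not given in the sources used here. Neighbouring probes differed by a median of 0.02 in the authors' values of the wild type stage 13 array and by 0.32 in the ratios of processed intensity, so the authors' values had been smoothed along the genome. One of the column names contains the word median, and whether this was taken over arrays or along the genome is not given in the sources used here. The authors' values were used only as an alternative. They were missing for 15.4% of genomic probes on the wild type stage 13 array and for 15.5% on each other stage 13 array. At stage 10B they were missing for 0.307%. Counts and means from the authors' values thus rest on fewer probes, and differ from the main ones in probe set as well as in normalization.

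The main measurement was log2 of egg chamber over embryo processed intensity, turned the same way on every array from the dyes in the labels and centred on the median of all genomic probes, with no loess or quantile step. Control spots were left out and saturated spots kept; the files marked 0 saturated probes. Profiles were means of probes within 5 kb, taken every 500 bp with at least 3 probes and interpolated otherwise. An amplified region was a run with smoothed log2 of at least 1 over at least 5 kb on arms 2L, 2R, 3L, 3R or X, and runs closer than 50 kb were merged. Each array had its own summit within 20 kb of the wild type stage 13 summit. Width was the distance between the nearest crossings of the level at 50% of the summit height above 1, on the linear scale.

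The within-array spread was taken from odd-ranked and even-ranked probes measured separately. A width difference was called beyond the spread only where the odd and even values of both arrays did not overlap. This covers measurement error within an array, not variation between egg chamber collections. With 1 array per group no p-values were computed. Several choices were made after values had been seen. Widths were given only where the summit reached 1.5-fold on both arrays, a region was called densely tiled from 20 probes per 10 kb, and the spread of a median over amplicons was the median of the odd-to-even differences of its members. The latter replaced the odd-to-even difference of the median itself, which came out close to 0 for 6X-SuUR.

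Flanks were means in rings around the wild type stage 13 summit. Each ring difference was set against 10000 random places of the same shape on the arms, at least 150 kb from amplicons and outside the centromere-proximal 1 Mb. Proximal and heterochromatic sequences were set against 10000 random windows of at most 1000 kb. A mean over 5 amplicons was set against 10000 means of 5 random places. A mean over the proximal ends of 5 arms was set against 10000 means of 5 random windows. Percentiles among random places describe these arrays and are not tests. Under-represented regions were runs of 100 kb means, taken every 10 kb with at least 20 probes, at or below -0.5. Differences between strains were also taken over 3389 windows of 10 kb with at least 5 probes on both arrays.

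No gene annotation of dm3 was used here, so genes were not placed. The rule for named genes, set before the data were examined, allowed windows of 10 kb in place of genes. For each stage 13 strain against wild type, it named the 10 windows with the largest positive and the 10 with the largest negative difference of at least 0.3, with at most 3 per 50 kb. Its fixed gene lists, and a planned reading of the SuUR and white genes, were not analysed here. Amplicon names (22B, 30B, 34B, 62D, 66D, 7F) were given to the densely tiled amplified regions by their order along each arm, from general knowledge of the known amplicons, and not by a gene annotation.

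The steps were tested on simulated data on the real probe positions with noise drawn from the wild type stage 13 array. Over 5 flat genomes the mean number of amplified calls was 0.6 and of under-represented calls 0. For simulated gradients of 3 to 30-fold height, the median recovered width lay between 0.86 and 1.08 times the true width, and for gradients of 10 and 30-fold between 0.945 and 1.08. For the window comparison, 200 of 200 shifted windows among 3389 passed an absolute difference of 0.5, as did 68 windows with no shift. Of 20 lowered stretches, 20 were found. The planted shifts and losses were larger than the thresholds, and the noise was drawn for each probe by itself. These counts thus do not measure how well weaker differences are found, nor false calls from noise that neighbouring probes share.

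Alternatives covered the authors' values, normexp background correction with offset 50, loess within the array, centring on euchromatic autosomal probes, leaving out dim and outlier probes, smoothing over 2 kb and 10 kb, other thresholds, other width levels and baselines, thinning of the stage 10B array, division by the summit, and a 500 kb proximal length. Probe values after subtracting the median of their GC class, the outermost crossing of the width level, restriction to the 5 densely tiled amplicons shared by the 4 stage 13 strains, and restriction of calls to densely tiled regions were added after the data had been seen. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1, the latter for normexp and loess.

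Median spot intensity over local background bounds the precision. For egg chamber DNA it was 641 over 51 in wild type stage 13, 680 over 53 in the SuUR mutant, 887 over 56 in 4X-SuUR, 552 over 53 in 6X-SuUR and 419 over 20 at stage 10B. For embryo DNA it was 256 over 18, 247 over 17, 223 over 17, 168 over 16 and 402 over 56 in the same order. Probes dim or marked as outliers in either channel made up 4.90% on wild type stage 13, 4.41% on the SuUR mutant, 4.96% on 4X-SuUR, 7.64% on 6X-SuUR and 22.9% at stage 10B. The number of arrays limits the precision of each comparison.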

Results

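DNA copy number along the genome was measured in ovarian egg chambers of Drosophila melanogaster. Late in oogenesis the follicle cells around the oocyte stop replicating the whole genome and re-replicate a few loci that carry eggshell and other genes. Forks leave each origin in both directions, so a locus shows a summit of copy number with a gradient on either side. SuUR (Suppressor of Underreplication) is a chromatin protein whose loss is known to restore copy number in under-replicated parts of polyploid chromosomes, and the series asked how SuUR affects fork progression in amplifying follicle cells. Egg chamber DNA was set against DNA of diploid Oregon R embryos on 5 arrays: stage 13 wild type (Oregon R), SuUR mutant, 4X-SuUR and 6X-SuUR, and stage 10B wild type. The names 4X-SuUR and 6X-SuUR are read here as strains of raised SuUR dosage. Each group had 1 array, so no difference below has a replicate check, and ranges in brackets are the values from odd-ranked and even-ranked probes of the same array.

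The 4 stage 13 arrays had the same sex-chromosome pattern. Probes on X had a median log2 ratio of 0.27 in wild type, 0.26 in the SuUR mutant, 0.26 in 4X-SuUR and 0.27 in 6X-SuUR. The 22 probes on Y-linked heterochromatin, a chromosome that females lack, had medians of -4.09, -3.02, -3.61 and -3.83 in the same order. On the stage 10B array the X median was 0.19, and the median of its 483 Y probes was -0.66.

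In wild type stage 13 egg chambers, 6 densely tiled loci were amplified. The summit of 66D, the locus of the third-chromosome chorion genes, lay at 3L 8719000 (dm3) and reached 29.6-fold (28.9 to 31.3). The summit of 7F, the locus of the X-linked chorion genes, lay at X 8371000 and reached 11.0-fold (11.3 and 10.9). The other summits were 34B at 2L 13404500 with 4.44-fold, 22B at 2L 1907500 with 2.94-fold, 30B at 2L 9547000 with 2.93-fold and 62D at 3L 2283500 with 2.80-fold. At 50% of the summit height above 1, the gradients were 36.2 kb wide at 66D, 44.7 kb at 7F, 36.7 kb at 34B, 37.7 kb at 22B, 63.1 kb at 30B and 53.0 kb at 62D. A further 2 calls lay in sparsely tiled sequence, on 3R with its summit at 17826500 and on X with its summit at 16901000, and they rested on few probes.

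**Figure D1:**
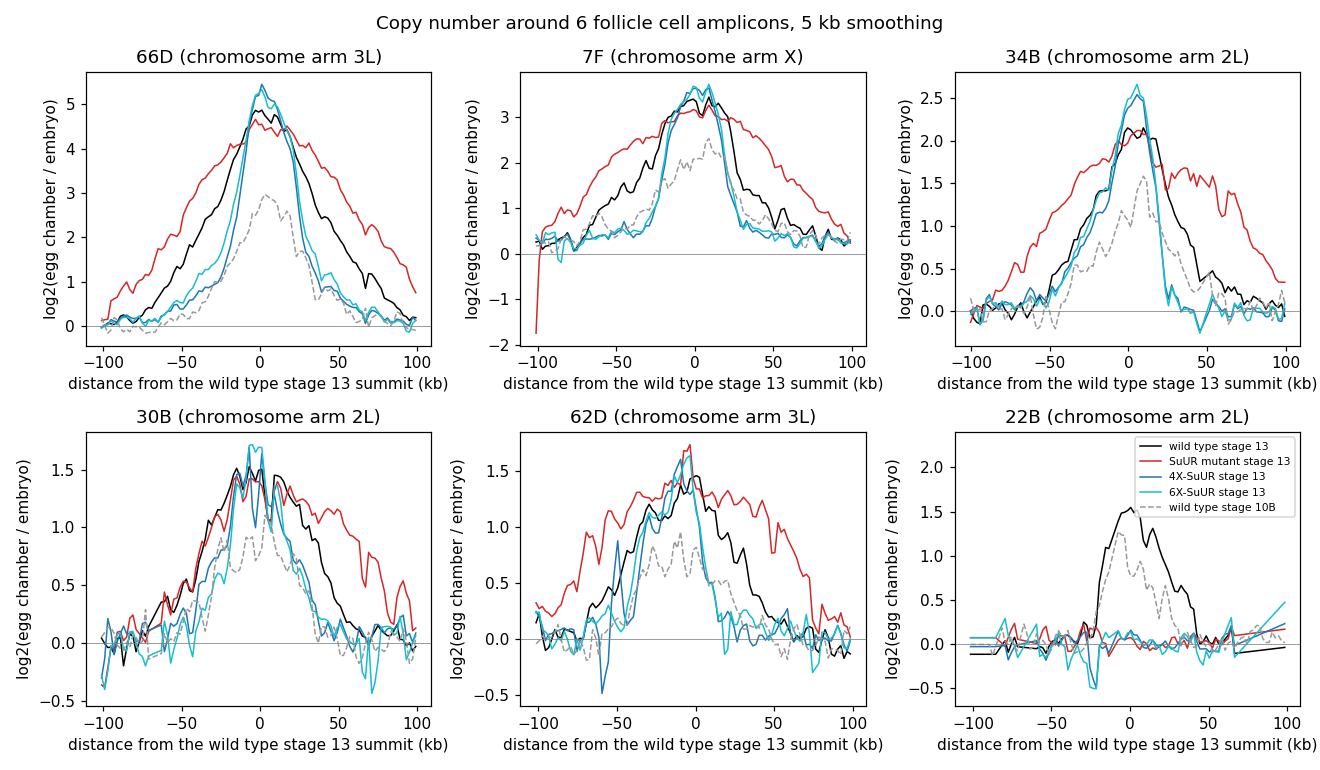
Copy number around 6 amplicons: log2 of egg chamber over embryo against distance in kb from the wild type stage 13 summit, smoothed over 5 kb, with 1 line per array. The SuUR mutant (red) lies above wild type (black) in the outer flanks of 5 amplicons (at 30B on the right side), 4X-SuUR and 6X-SuUR (blue and cyan) lie below it (at 34B mainly on the right side), and 22B has a summit only in the wild type arrays.

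The comparison of the SuUR mutant with wild type at stage 13 asked whether gradients change in width without SuUR. The mutant gradients reached farther at 5 of 5 densely tiled amplicons, with summits from 0.868 to 1.19 times those of wild type. Widths were 60.7 kb against 36.2 kb at 66D, 69.9 against 44.7 at 7F, 58.9 against 36.7 at 34B, 89.2 against 63.1 at 30B and 79.7 against 53.0 at 62D. The median width ratio over these 5 was 1.57, from 1.41 to 1.68. The difference was beyond the odd and even probe spread at 66D, 7F, 34B and 30B but not at 62D, where the mutant values were 92.5 and 44.9 kb. At this level the added width lay on the left side of 34B and on the right side of 30B. The opposite crossings of these amplicons stayed at about the wild type position. With the sparsely tiled X 16901000 region, at 0.642, the median was 1.53. The outermost crossings gave that region 1.16. Smoothing over 2 kb in place of 5 kb left a median ratio of 1.06.

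Summit folds in the mutant were 25.7 at 66D, 9.61 at 7F, 4.37 at 34B, 2.85 at 30B and 3.34 at 62D, and the median ratio to wild type was 0.974. Its direction was not settled, since loess gave 1.13 and the authors' values gave 1.06. Odd and even folds lay below those of wild type at 66D and 7F, but loess and the authors' values turned both to above wild type. They lay above those of wild type at 62D and 34B, although the fold of 34B from all probes was lower. Farther out the mutant held more DNA than wild type. The mean log2 difference over the 5 amplicons was -0.06 within 10 kb of the wild type summits and 0.02 from 10 to 20 kb. It was 0.37 from 20 to 30 kb, 0.66 from 30 to 40 kb and 0.79 from 40 to 50 kb. The last 2 lay above all 10000 means of 5 random places, which averaged 0.05. In the ring from 30 to 40 kb, the difference was 1.04 at 66D, 1.00 at 7F, 0.69 at 34B, 0.45 at 62D and 0.11 at 30B. With each profile's fold above 1 divided by that at its summit, the mutant's flank at 30 to 40 kb was also higher, by 0.25 of the summit height, a share that is not comparable with log2 differences.

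The 22B amplicon had no summit in the mutant. Its highest fold within reach was 1.102 in the SuUR mutant, 1.117 in 4X-SuUR and 1.113 in 6X-SuUR, against 2.94 in wild type stage 13 and 2.42 in wild type stage 10B. Widths of 22B were therefore compared only between the wild type arrays.

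**Figure D2:**
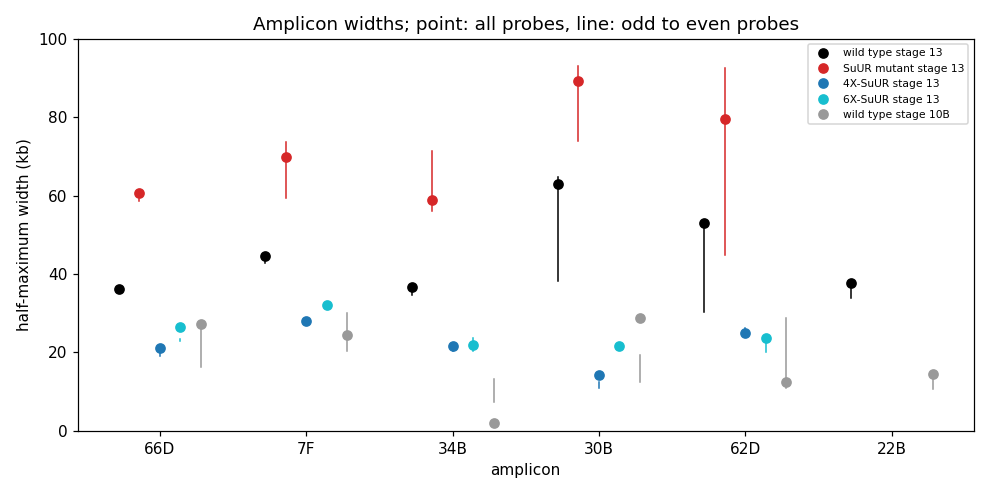
Width in kb at 50% of the summit height above 1 for 6 amplicons, with 1 point per array from all probes and a line from the odd-probe to the even-probe value. The mutant points, from 58.9 to 89.2 kb, lie above wild type stage 13, and those of 4X-SuUR and 6X-SuUR, from 14.3 to 32.1 kb, lie below it.

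Away from the amplicons, log2 ratios over several repeat-rich sequences were closer to 0 in the mutant than in wild type. The Y probes, for which female tissue has no target, rose by 1.27 as well, so these differences need not all be differences in copy number. The mean log2 ratio was -0.16 against -0.63 over the 100 probes of 2RHet and -0.19 against -0.69 over the 86 probes of 3LHet. It was -1.04 against -1.38 over the 85 probes of 3RHet and -1.72 against -2.48 over the 103 probes of unplaced sequence. The mean difference over these 4 was 0.51. Chromosome 4 went the other way, with -0.05 against 0.16, as did the 22 probes of XHet, with 0.29 against 0.45. Wild type stood above the other strains whatever their dosage at both, since 4X-SuUR and 6X-SuUR differed from it by -0.11 and -0.10 on chromosome 4 and by -0.20 and -0.24 at XHet. Over the centromere-proximal 1 Mb of 5 arms the mean difference was -0.02, at percentile 76.0 of means of 5 random windows. It was positive with the authors' values, at 0.077. Only 3L was higher in the mutant there, by 0.18.

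Of the 3 regions called under-represented in wild type, 2 were close to the genome median in the mutant. In bounds merged over the stage 13 arrays, the 3456 probes of 2L 16940001 to 17370000 had a mean log2 ratio of -0.49 in wild type and -0.11 in the mutant. At 3L 13540001 to 13870000 the means were -0.37 and -0.10. Wild type and mutant each had 3 called regions on the arms, covering 570 and 450 kb. They shared 1, the 24 probes at 3L 1 to 130000, with -0.43 in wild type and -0.68 in the mutant. At the weaker threshold of -0.3 the counts were 35 in the mutant and 12 in wild type. The mutant had 0 called regions with the authors' values (wild type 1), with normexp (wild type 5) and without dim and outlier probes (wild type 2). The other regions called in the mutant, 3L 1420001 to 1550000 and 3L 9710001 to 9900000, had 29 and 46 probes.

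Among 3389 windows of 10 kb the mutant differed from wild type by more than 0.5 in 159, higher in 84 and lower in 75, and the SD of all differences was 0.26. The count was 71 with the authors' values and 103 without dim and outlier probes, and 68 windows with no shift passed in the simulated comparison. Of the 10 named windows with the largest gains, the first 4 lay near no known amplicon. They were 3 windows within 2L 12870001 to 12900000, with differences of 1.41, 1.36 and 1.32, and 3L 9200001 to 9210000, with 1.34 over 6 probes. These windows were gained in the raised-dosage strains too, by 1.102 to 1.46 in 4X-SuUR and 1.28 to 1.65 in 6X-SuUR. The other 6 lay within 150 kb of a known amplicon and included X 8400001 to 8410000 beside 7F, with a difference of 1.30, and 3L 8790001 to 8800000 beside 66D, with 1.14. The window with the largest loss was X 8260001 to 8270000, where 78 probes had -1.68 in the mutant and 0.13 in wild type. A further 2 of the named losses were at 22B.

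The comparisons of 4X-SuUR and 6X-SuUR with wild type at stage 13 asked what raised SuUR dosage does to the gradients. Gradients were narrower and summits higher at 5 of 5 densely tiled amplicons in both strains, with the odd and even folds of 62D in 4X-SuUR (3.28 and 2.92) overlapping those of wild type (2.98 and 2.74). At 66D the width was 21.3 kb in 4X-SuUR and 26.5 kb in 6X-SuUR, against 36.2 kb in wild type, and at 7F it was 28.2 and 32.1 kb against 44.7 kb. At 34B the widths were 21.7 and 22.01 kb, at 30B 14.3 and 21.7 kb, and at 62D 25.1 and 23.8 kb. The 14.3 kb at 30B ended at a local dip 2.97 kb right of the summit, within a called region of 32 kb. With the outermost crossings the width ratio of 30B was 0.462 in place of 0.227 in 4X-SuUR and 0.462 in place of 0.345 in 6X-SuUR. The median width ratio over these 5 was 0.588 in 4X-SuUR and 0.600 in 6X-SuUR, and each of the 10 differences was beyond the odd and even probe spread.

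Including the sparsely tiled X 16901000 region, at 0.844 and 1.15, the medians were 0.589 and 0.660. The outermost crossings gave that region 2.08 in 4X-SuUR and 1.51 in 6X-SuUR. Smoothing over 2 kb turned the ratio of 7F to 1.45 in 4X-SuUR and 1.73 in 6X-SuUR, and normexp background correction turned that of 62D to 1.15 in 4X-SuUR. Summits reached 43.7-fold in 4X-SuUR and 40.2-fold in 6X-SuUR at 66D, 13.3 and 13.2-fold at 7F, 6.04 and 6.57-fold at 34B, 3.23 and 3.34-fold at 30B and 3.09 and 3.26-fold at 62D. The median summit ratio to wild type was 1.21 in 4X-SuUR and 1.20 in 6X-SuUR.

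The flanks of both strains fell below wild type from 10 kb outward. The mean difference over the 5 amplicons was -0.37 in 4X-SuUR and -0.26 in 6X-SuUR from 10 to 20 kb, -0.80 and -0.69 from 20 to 30 kb, -0.80 and -0.70 from 30 to 40 kb and -0.60 and -0.57 from 40 to 50 kb. Within 10 kb of the wild type summits it was 0.09 in 4X-SuUR, higher at 3 of 5 amplicons, and 0.14 in 6X-SuUR, higher at 4 of 5, and 62D was lower in both, by -0.26 and -0.19. From 20 kb outward these means lay below all 10000 means of 5 random places in both strains. In the ring from 30 to 40 kb, 66D differed by -1.55 in 4X-SuUR and -1.18 in 6X-SuUR, and 62D by -0.42 and -0.23. With the fold above 1 divided by that at the summit, the differences at 30 to 40 kb were -0.21 and -0.20 as shares of the summit height.

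Over the 4 stage 13 strains, the mutant was wider than wild type and wild type wider than both raised-dosage strains at 5 of 5 amplicons. The order of the raised-dosage strains did not follow their names. 6X-SuUR was narrower than 4X-SuUR at 1 of 5 amplicons, 62D, and the odd and even widths of the 2 strains overlapped at 34B. At 30B the order rested on the nearest crossing, since the outermost crossings gave both strains the same ratio.

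Under-represented stretches were more numerous in the raised-dosage strains. On the arms, 16 regions covering 3340 kb were called in 4X-SuUR and 14 covering 2490 kb in 6X-SuUR, against 3 covering 570 kb in wild type. The wild type stage 10B array, of another design, had 8 covering 1550 kb. Of 25 regions merged over the stage 13 arrays, 8 were called in both strains and 2 of these also in wild type. That both strains lie below wild type in these 8 follows largely from how they were picked. Over the 3 regions called in wild type, which the raised-dosage arrays did not choose, the mean difference was 0.09 in 4X-SuUR (SD 0.69) and 0.04 in 6X-SuUR (SD 0.70). Both strains were lower at 2 of the 3 and higher at the other, 3L 1 to 100000. There the means were 0.39 in 4X-SuUR and 0.34 in 6X-SuUR against -0.50 in wild type. At 2L 16980001 to 17290000 they were -0.93 and -0.86 against -0.59, and at 3L 13630001 to 13790000 -0.79 and -0.96 against -0.51. In the merged bounds, which the raised-dosage calls helped to set, the means at 2L 16940001 to 17370000 were -0.79 and -0.71 against -0.49. At 3L 13540001 to 13870000 they were -0.63 and -0.68 against -0.37. At 2L 14690001 to 15020000 they were -0.85 and -0.33 against -0.25, and at 3R 23810001 to 24110000 they were -0.72 and -0.40 against -0.31. The mutant was the highest of the stage 13 strains in 7 of the 8. With the authors' values the counts were 10 in 4X-SuUR, 5 in 6X-SuUR, 1 in wild type and 0 in the mutant. A region called in 6X-SuUR at X 2610001 to 2890000 was of another kind, with -1.75 against 0.42 in wild type.

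**Figure D3:**
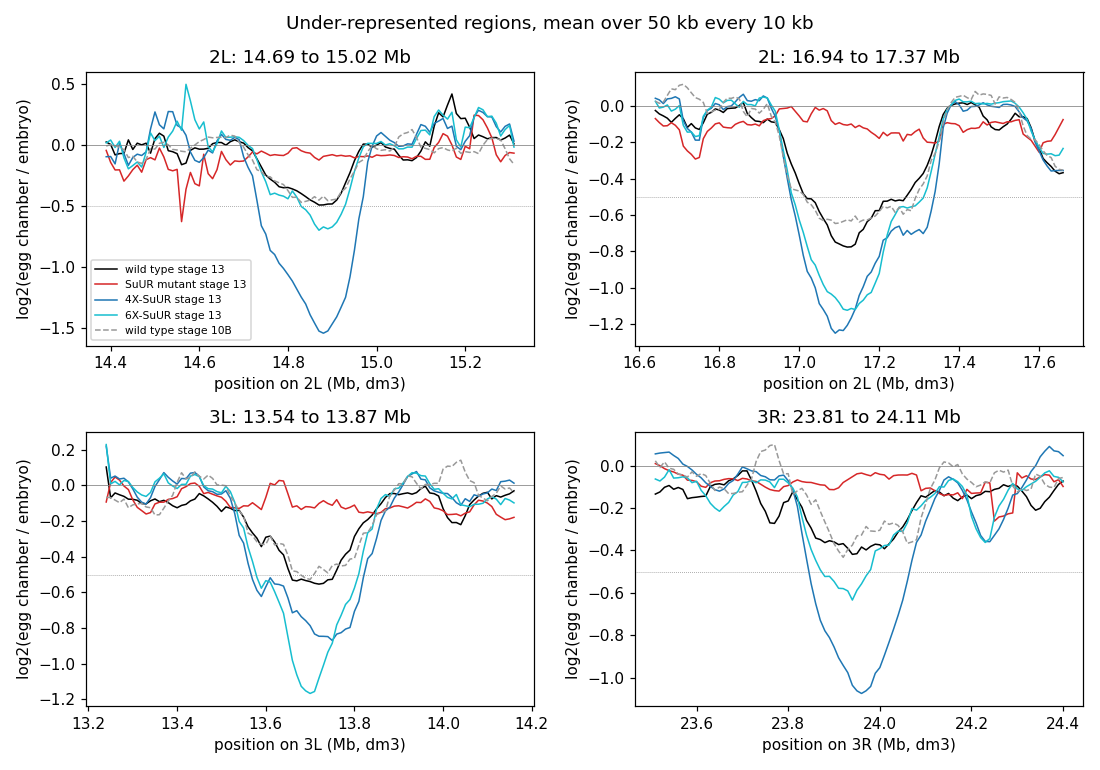
Mean log2 of egg chamber over embryo in 50 kb windows every 10 kb against position in Mb (dm3) for 4 regions called under-represented in both 4X-SuUR and 6X-SuUR, with 1 line per array. The dotted line marks -0.5. The SuUR mutant stays near 0 in each region, and over the deepest part of each region wild type lies below it and both raised-dosage strains lie below wild type.

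Heterochromatic sequences were lower in the raised-dosage strains at some places only. Over the centromere-proximal 1 Mb of 5 arms the mean difference from wild type was -0.15 in 4X-SuUR and -0.21 in 6X-SuUR. These lay at percentiles 0.08 and 0.03 of means of 5 random windows. With the authors' values, which are missing for 15.5% of the probes on both arrays, the differences were -0.0053 and -0.067. Most of the main difference came from 3L, whose 71 proximal probes differed by -0.50 and -0.57. The proximal X differed by -0.09 in 4X-SuUR and -0.34 in 6X-SuUR. At 2RHet the differences were -0.20 and -0.26 and at 3LHet -0.35 and -0.50. At 3RHet they were -0.11 and 0.05 and over unplaced sequence 0.05 and 0.04. The Y probes were higher than in wild type in both strains, by 0.47 and 0.55.

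**Figure D4:**
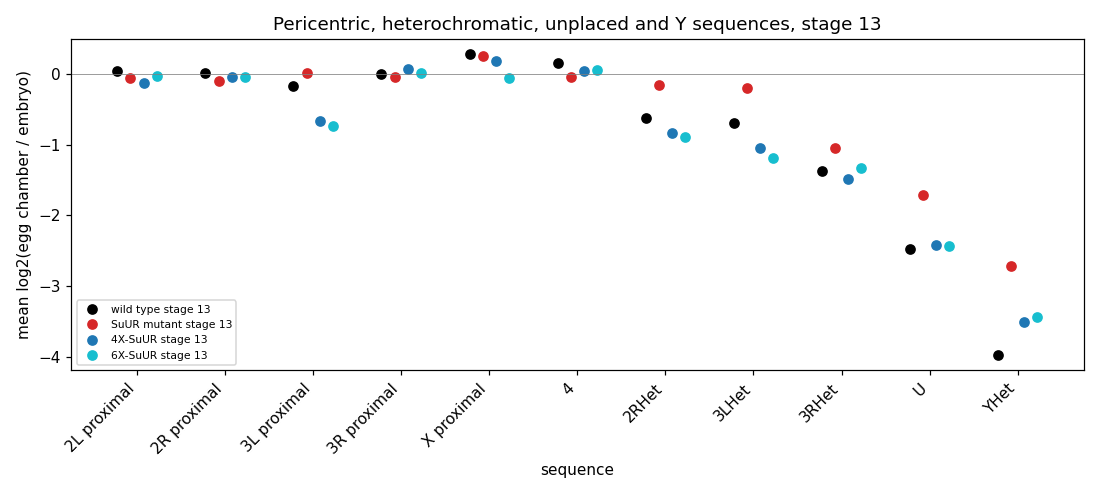
Mean log2 of egg chamber over embryo over centromere-proximal, heterochromatic, unplaced and Y sequences, with 1 point per stage 13 array. The mutant lies above wild type at 3L proximal, 2RHet, 3LHet, 3RHet, unplaced and Y sequence, and 4X-SuUR and 6X-SuUR lie below wild type at 3L proximal, 2RHet and 3LHet.

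Windows of 10 kb differed from wild type by more than 0.5 in 186 of 3389 in 4X-SuUR, higher in 30 and lower in 156, with an SD of 0.26. In 6X-SuUR 140 windows did so, higher in 40 and lower in 100, with an SD of 0.29. The authors' values gave 81 windows in 4X-SuUR and 42 in 6X-SuUR, and leaving out dim and outlier probes gave 118 and 67. The named losses of 4X-SuUR included 5 windows near known amplicons, such as 3L 8690001 to 8700000 beside 66D with a difference of -1.74. None of the 10 named gains of either strain lay near a known amplicon, and 7 of 10 in each strain rested on fewer than 20 probes. The 5 windows with the largest losses in 6X-SuUR lay within X 2710001 to 2820000, where 40 probes averaged -3.97 in 6X-SuUR, 0.28 in 4X-SuUR and 0.40 in wild type. In 4X-SuUR a named gain at 3R 11770001 to 11780000, at 1.09, was -0.10 without dim and outlier probes.

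The comparison of wild type stage 10B with wild type stage 13 asked how far gradients had spread at the earlier stage. Summits were lower and gradients narrower at 6 of 6 amplicons at stage 10B, although normexp background correction turned the width ratio of 62D to 1.36. The summit was 8.09-fold against 29.6-fold at 66D, 6.01 against 11.0 at 7F, 3.45 against 4.44 at 34B, 2.42 against 2.94 at 22B, 2.15 against 2.93 at 30B and 1.95 against 2.80 at 62D. Widths were 27.2 kb at 66D, 24.4 kb at 7F, 28.8 kb at 30B, 14.5 kb at 22B and 12.4 kb at 62D. At 34B the nearest crossings were 2.00 kb apart, below the 13.2 and 7.36 kb of odd and even probes, so this width is a property of noise at the summit. The odd and even widths of 62D were 11.0 and 28.8 kb. With the outermost crossings the width ratio was 0.709 in place of 0.235 at 62D and 0.808 in place of 0.456 at 30B. It was 0.627 in place of 0.385 at 22B, 0.730 in place of 0.546 at 7F and 0.736 in place of 0.751 at 66D. The median width ratio was 0.421, and 0.720 with the outermost crossings. Y probes, though not the same ones, had a median of -0.66 at stage 10B against -4.09 at stage 13, and stage cannot be told apart from array design, dye orientation and batch. Whole egg chambers also hold germline DNA, including that of the polyploid nurse cells, and its share was not measured here.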

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

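The tests of the sparsely tiled regions, of the age of the egg chambers and of compression on the mutant array were chosen after the results were seen; so was the subtraction of GC classes, although what it should show was set before its own result, as it was for stretched log ratios and the choice of regions by depth.

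Amplified calls outside the regions of wild type stage 13 drew attention because the wild type stage 10B array had 0 of them. There were 17 in the SuUR mutant, 20 in 4X-SuUR and 36 in 6X-SuUR, with a median of 4 probes each, and 17, 19 and 35 of them lay in sparsely tiled sequence; total calls were 8 in wild type stage 13 against 22, 25 and 41, but 6 against 5, 6 and 7 with the authors' values, 6 against 5, 11 and 14 without dim and outlier probes, and 22 against 8, 23 and 20 with normexp. Their embryo signal was read on the wild type stage 13 array, which entered their definition only by not calling them. It had a median of -1.07 log2 units against the array median. Of the 73 regions, 53.4% lay at or below -1, against 3.74% of runs of 4 sparse probes. A place shared between strains was counted once per strain: 12 regions in the mutant, 13 in 4X-SuUR and 17 in 6X-SuUR overlapped one of another strain. Probes dim in embryo DNA on 1 array may be dim on all, so this signal was not independent of the calls. Of the 17 regions in the mutant, 12 overlapped a region of 4X-SuUR or 6X-SuUR, against a mean of 1.56 and a highest value of 6 in 1000 placements at sparse probes of like embryo signal (0.227 and 3 without that matching), which argues against noise that is independent between arrays but not against a bias that dim probes repeat on each array. Sequence that is missing or diverged in Oregon R, and present in the backgrounds of the other strains, may account for many of these calls, and a repeated bias of dim probes stays open; no biological explanation was tested.

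The wider gradients of the mutant and the narrower ones of 4X-SuUR and 6X-SuUR were weighed against technical explanations. Stretching or compression of an array's log ratios would leave the flank at the same share of the summit, but relative to wild type the median share over 5 amplicons was 1.41 in the mutant, 0.411 in 4X-SuUR and 0.414 in 6X-SuUR. After subtraction of GC classes the median width ratios were 1.56, 0.545 and 0.563, so GC content did not account for them. Younger egg chambers in the raised-dosage strains were predicted to have lower summits. Summits were instead above wild type at 5 of 5 amplicons in 4X-SuUR and at 5 of 5 in 6X-SuUR. They were beyond the odd and even probe spread at 4 and 5. At 62D, however, the mean within 10 kb of the wild type summit was lower in both strains, by -0.26 and -0.19. This cannot decide the age, since whether only slightly younger egg chambers have lower summits was not measured. The share of germline DNA, which also affects summit height, was not measured either. Younger egg chambers in the raised-dosage strains thus stay open, and older ones in the mutant were not tested. An effect of SuUR on how far forks travel was not tested and stays a hypothesis. The mutant was wider than wild type, and wild type wider than both raised-dosage strains, at 5 of 5 amplicons. 6X-SuUR was narrower than 4X-SuUR at only 1 of 5. The SuUR gene was not read and each strain had 1 array, so this order cannot decide whether dosage has a graded effect. Differences in strain background, and between collections with 1 array each, stay open too.

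Under-represented stretches that were deeper in the raised-dosage strains, among the regions called there, and shallower in the mutant were weighed in the same way. Over the 16 regions chosen on 4X-SuUR, that strain differed from wild type by a mean of -0.37. The 6X-SuUR array, which did not choose them, differed by -0.15 (SE 0.037) and was lower in 13. Choice by depth may thus account for much of the -0.37. The -0.15 fell short of the -0.2 set beforehand to exclude such a choice, so that test did not decide. The SE is over regions with 1 array per strain and does not cover differences between arrays. After subtraction of GC classes the mean difference of 6X-SuUR was -0.15 (SE 0.038), so GC content did not remove it, although this again fell short of -0.2. In the 2 densely tiled regions called on wild type, the mutant kept 0.198 of the log2 deficit, against 0.682 over Y probes, which argues against compression of low log ratios there. The shares over unplaced sequence, 0.693, and 3RHet, 0.756, were close to that of the Y probes, so compression stays open for the gains there, whereas those at 2RHet, 0.255, and 3LHet, 0.282, lay far below it; an effect of SuUR on under-replication, strain background and the share of nurse cell DNA were not tested and stay open.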

How the results depend on the processing

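The densely tiled regions, the outermost crossing and the GC classes were alternatives added after the results were seen; the others were set before the data were examined. Median width ratios to wild type stage 13 kept their direction under all 14 alternatives in each group. They ranged from 1.06 to 1.78 in the SuUR mutant, 0.535 to 0.750 in 4X-SuUR, 0.600 to 0.793 in 6X-SuUR and 0.028 to 0.781 at stage 10B. Flank differences at 30 to 40 kb kept their direction under all 7 alternatives in each strain, as did the mean difference over 2RHet, 3LHet, 3RHet and unplaced sequence under 5. The authors' values are not among these 5, since too few probes had them there. The proximal difference of the mutant kept its sign under 3 of 7, and its median summit ratio stayed below 1 under 5 of 7. The readings of SuUR and white, and of gene lists, were not run. No paired analysis was possible because each group has 1 array. Median spot intensity of embryo DNA before any comparison with background was lowest in 6X-SuUR, at 168 over a background of 16. The stage 10B array, at 402 over 56, had the highest background of embryo DNA. It also had the most dim or outlier probes, 22.9% against 7.64% in 6X-SuUR. Dim probes limit the sparsely tiled regions. Of 251 values of main results under alternatives, 92 moved by more than the spread or by more than 1.5 times and 159 did not. Among the other values, 289 moved, 9 turned direction and 415 did neither. The turns of the mutant's proximal difference and median summit ratio are not among these 9, since their main values lay within their spread of no difference. The 159 main values counted as not moved include the mutant's median width ratio with 2 kb smoothing, 1.06 against 1.53. Its spread was a typical odd-to-even difference of single amplicons, which is wide, so this count does not show that the ratio was stable. Named window values kept their sign in 94 of 94 cases in the mutant, 88 of 89 in 4X-SuUR and 83 of 83 in 6X-SuUR. Except where the construction of the alternative shows it (other thresholds, fewer probes or regions), the cause was not tested for any value that follows.

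With the authors' deposited values, amplified calls numbered 5 in the mutant, 6 in 4X-SuUR and 7 in 6X-SuUR, and under-represented calls 1 in wild type stage 13, 0 in the mutant, 10 in 4X-SuUR and 5 in 6X-SuUR. The summit ratio of the mutant turned to 1.06 at 66D and 1.03 at 7F. Median summit ratios were 1.06 in the mutant and 1.31 in 4X-SuUR. Flank differences were 0.75 in the mutant, -0.71 in 4X-SuUR and -0.63 in 6X-SuUR. Proximal differences were 0.077, -0.0053 and -0.067. Windows past 0.5 numbered 71 in the mutant, 81 in 4X-SuUR and 42 in 6X-SuUR, and the SD of window differences in 6X-SuUR was 0.17.

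With normexp, amplified calls numbered 22 in wild type stage 13, 8 in the mutant and 20 in 6X-SuUR, and under-represented calls 5 in wild type stage 13 and 0 in the mutant. The width ratio of 62D turned to 1.15 in 4X-SuUR and 1.36 at stage 10B, where the median width ratio was 0.703. Median summit ratios were 1.42 in 4X-SuUR, 1.11 in 6X-SuUR and 0.504 at stage 10B. Flank differences were 0.84 in the mutant and -0.79 in 6X-SuUR. Proximal differences were -0.076 in 4X-SuUR and -0.16 in 6X-SuUR, and heterochromatic ones -0.082 and -0.034.

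With loess, the summit ratio of the mutant turned to 1.15 at 66D and 1.06 at 7F. Median summit ratios were 1.13 in the mutant, 1.33 in 4X-SuUR, 1.32 in 6X-SuUR and 0.739 at stage 10B, and flank differences 0.77 in the mutant and -0.62 in 6X-SuUR. Without dim and outlier probes, amplified calls numbered 5 in the mutant, 11 in 4X-SuUR and 14 in 6X-SuUR, and under-represented calls 0 in the mutant and 9 in 6X-SuUR. Median summit ratios were 0.926 in the mutant and 0.658 at stage 10B. Heterochromatic differences were -0.21 in 4X-SuUR and -0.23 in 6X-SuUR. Windows past 0.5 numbered 103 in the mutant, 118 in 4X-SuUR and 67 in 6X-SuUR, where the SD was 0.19. The window 3R 11770001 in 4X-SuUR turned to -0.10. Centring on euchromatic autosomal probes left 1 under-represented region in wild type stage 13 and 7 in 6X-SuUR.

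Smoothing over 2 kb gave 13 amplified calls in the mutant, 15 in 4X-SuUR and 22 in 6X-SuUR. It turned the width ratio of 7F to 1.45 in 4X-SuUR and 1.73 in 6X-SuUR, and median summit ratios were 0.902 in the mutant and 1.36 in 6X-SuUR. Smoothing over 10 kb gave a median summit ratio of 0.934 in the mutant and a median width ratio of 0.766 at stage 10B. The latter was 0.781 at 25% of the summit height and 0.720 with the outermost crossing. A level common to all arrays gave median width ratios of 0.750 in 4X-SuUR, 0.793 in 6X-SuUR and 0.028 at stage 10B. Division by the summit changed the unit to a share of the summit's fold above 1, so its flank differences of 0.25 in the mutant, -0.21 in 4X-SuUR and -0.20 in 6X-SuUR cannot be set against the log2 differences in size; their direction was the same.

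Amplified calls from a log2 of 0.58 numbered 111 in wild type stage 13, 90 in the mutant, 152 in 4X-SuUR, 194 in 6X-SuUR and 19 at stage 10B. From 1.5 they numbered 4, 7, 6, 10 and 2 in the same order. Densely tiled calls numbered 5 in the mutant, 6 in 4X-SuUR and 6 in 6X-SuUR. Under-represented calls from -0.3 numbered 12 in wild type stage 13, 35 in the mutant, 49 in 4X-SuUR and 41 in 6X-SuUR. Over the proximal 500 kb the mutant differed by 0.063 and 6X-SuUR by -0.26. After subtraction of GC classes, the proximal difference of the mutant was 0.026, and heterochromatic differences were 0.57 in the mutant and -0.12 in 4X-SuUR.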

Other observations

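The intervals named here were singled out after their values were seen. At 2L 12870001 to 12900000, 242 probes had a mean log2 ratio of -0.54 in wild type stage 13 and -0.54 in wild type stage 10B. The same probes had 0.83 in the SuUR mutant, 0.59 in 4X-SuUR and 0.78 in 6X-SuUR. This interval and the 22B amplicon thus separated both wild type arrays from the other 3 strains, whatever their SuUR dosage.

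On 2R and 3L, 4 intervals were called amplified in both raised-dosage strains and in neither wild type stage 13 nor the mutant. At 2R 992001 to 997000, 12 probes had 1.97 in 4X-SuUR and 2.31 in 6X-SuUR, against 0.19 in wild type stage 13 and -0.98 in the mutant. At 3L 11055001 to 11078000, 6 probes had 1.09 in 4X-SuUR and 1.12 in 6X-SuUR, against 0.23 in wild type stage 13 and 0.28 in the mutant. At 3L 640501 to 664500, 6 probes had 0.68 in 4X-SuUR and 0.64 in 6X-SuUR, against -0.16 in wild type stage 13. Odd and even probes differed there, at 0.06 and 1.29 in 4X-SuUR and 0.24 and 1.04 in 6X-SuUR. At 3L 9964001 to 9975500, 3 probes had 1.20 in 4X-SuUR and 1.26 in 6X-SuUR, and also 1.03 in the mutant, against -0.13 in wild type stage 13. Which genes lie there was not analysed here.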
